A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

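RNA from budding yeast was measured in 6 samples, 3 untreated and 3 treated with zymolyase. Per the labels, about 500 ng of total RNA was turned into biotin-labelled antisense RNA with a 3' in vitro transcription kit and hybridised to Affymetrix arrays, 1 sample per array. The labelling starts at the 3' end of a transcript, so shortened RNA can change the signal of a probe set according to its distance from that end. The deposited values are signal intensities per probe set on a linear scale, computed by the authors with MAS5, per the submitters' processing notes, which state no version. MAS5 sets mismatch against perfect-match probes and scales each array by 1 factor, so a change in total messenger RNA per cell cannot be seen. In the deposited table the mean after trimming 2% at each end was between 500.41 and 500.43 on every array, so the deposited scaling was kept. Detection calls and scanner files were not used here. No pair of the 15 pairs of arrays held identical values.

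Columns were assigned to samples by accession and groups were taken from the sample titles. Of 10928 probe sets, 166 were controls, 5498 had 1 gene of S. cerevisiae by the platform's annotation and the RefSeq gene table of assembly R64, and 3517 were not listed in that annotation and stay unnamed here. A further 1747 carried genes absent from the S. cerevisiae table, 1 of them several genes. This array design also carries probe sets for Schizosaccharomyces pombe, and these 1747 were taken as the second species and used as background. Identifying them rests on that absence, not on a species column. S. cerevisiae probe sets were kept where the mean signal over all 6 arrays exceeded the 90th percentile of the second-species means, a signal of 10.1. This removed 104 and left 5394 probe sets for 5349 genes. Where a gene had several probe sets, the brightest stood for it in lists and among named genes.

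Log2 signals without an offset were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), zymolyase minus control, and p-values were adjusted by Benjamini-Hochberg. The threshold was an adjusted p of 0.05. A group below the second-species 99th percentile on all of its arrays was called not well above background. Its fold is then a lower bound: the mean log2 signal of the brighter group minus that of the dimmer group with each dim array set to the higher of its own signal and that percentile. No fold is given where the bound is under 1 or both groups are below background. The same bound, fixed after the data were seen, is given for named genes with 2 of 3 arrays of a group below that percentile, and no fold where this holds for both groups.

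The text names the 15 largest rises and 15 largest falls among genes that passed the test with every zymolyase array above, or every one below, all control arrays. It also names the 4 members of each list with the largest absolute log2 fold change, further members where a list needed them, and 14 genes fixed in advance. The gene lists and this rule were fixed before the data were examined. Of 748 gene names in the lists, 744 matched a locus, some through older symbols. Lists with at least 5 measured members, 32 of 33, were tested with camera at its preset correlation of 0.01, adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the few arrays instead of the many genes. A call lost under it is therefore not by itself a sign of correlated members. Fry asks whether the members of a list move on balance in a direction and does not compare the list with other genes.

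RNA integrity was read from the ratio of 3' to 5' control probe sets, with ACT1 as the gene tested and 7 more beside it. Exact permutation tests over the 6 arrays were two-sided and cannot give a p under 0.1. Gene lengths were taken from the RefSeq table for all 5394 probe sets. As 96.8% of them are multiples of 3 they hold no untranslated regions, and they are called coding length, introns included.

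Alternatives were an offset of 50, quantile normalization, median centring, no filter and a 99th percentile filter, no intensity trend, the replicate number as a block, and each array left out in turn. Removing the gene length trend, leaving out the 121 probe sets that can match several transcripts, and leaving out each array for the RNA integrity ratio were chosen after seeing the data. The length trend was removed per array with a local regression (span 0.5, degree 1) of each probe set's deviation from its mean on log2 length. The procedure was tested on simulated arrays of this comparison with 5394 probe sets, 200 of them changed. It found 93 of 100 changes of 1 and 72 of 100 changes of 0.5 on the log2 scale, with 10 false calls. These rates need not hold for the real arrays, where 3857 probe sets were called and trends across whole arrays were present. Among 32 simulated lists of 20 members the procedure found the 1 raised list and no other, but simulated genes vary independently, which real members of a list need not. On the other 9 splits of the real arrays into 3 and 3, limma called 0 genes and the same camera test passed 5 to 10 lists. Each such split mixes the groups, so it keeps part of the real contrast and puts the rest within its sides. Neither count is therefore a rate of false calls, and the simulation of independent genes gives none for real lists. Only 2 groups were given in the labels, with no batch or scan information, so batch effects could not be examined.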

Results

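Gene expression was measured in budding yeast, Saccharomyces cerevisiae, with and without zymolyase, an enzyme mixture that digests the glucan of the fungal cell wall. Cultures were grown in rich medium at 25 °C for 2 days, per the labels. The treated cells received zymolyase at 30 U/ml for 10 min at 37 °C, and untreated cells were the control. Each group held 3 samples, each hybridised to its own Affymetrix array, so that 6 arrays were compared. The question was which transcripts differ after enzymatic digestion of the wall. The labels call the digestion the only difference between the groups, and they do not state the temperature of the control cells at that step. A step to 37 °C can therefore not be told apart from the enzyme for any gene below. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples. All values below are MAS5 signals in intensity units, and ± after a signal is the SD of 3 arrays. Of 10928 probe sets, 5394 for named S. cerevisiae genes were above background and were tested. The number of arrays limits the precision.

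Array correlations of log2 signal were between 0.985 and 0.987 within a group and between 0.938 and 0.947 across groups. Signals of probe sets designed for a second species, which measure cross-hybridisation, had a 99th percentile between 21.0 and 31.4 per array. Between 94.0% and 95.5% of the S. cerevisiae probe sets lay above that percentile of their own array.

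The cultures were labelled BY4743, a laboratory strain given in the labels as an a/α diploid lacking URA3 and LEU2, genes of uracil and leucine synthesis. On these arrays the URA3 signal was 1802 ± 66.8 in the control and 1783 ± 124 with zymolyase. The corresponding LEU2 signals were 671 ± 38.5 and 813 ± 57.9. Neither gene was at background, since on its lowest array URA3 was 55.0 times and LEU2 26.1 times the second-species 99th percentile. HIS3, MET17 (also MET15) and LYS2, also listed as mutated, were at least 35.1, 97.3 and 18.9 times that percentile. The HIS3 allele of this strain lacks an internal part of the gene, so its signal checks nothing by itself, and BY4743 keeps a copy of MET17 and of LYS2. Genes of the α mating type were bright: the pheromone gene MF(ALPHA)1 gave 13248 ± 1346 and the receptor gene STE3 3035 ± 89.7 in the control. The a-type genes STE2 and MFA1 gave 48.4 ± 11.1 and 32.8 ± 6.94. HO and RME1, which are repressed in a/α diploids, gave 1214 ± 65.2 and 2049 ± 152. The strain is therefore called the strain labelled BY4743 in what follows.

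**Figure D1:**
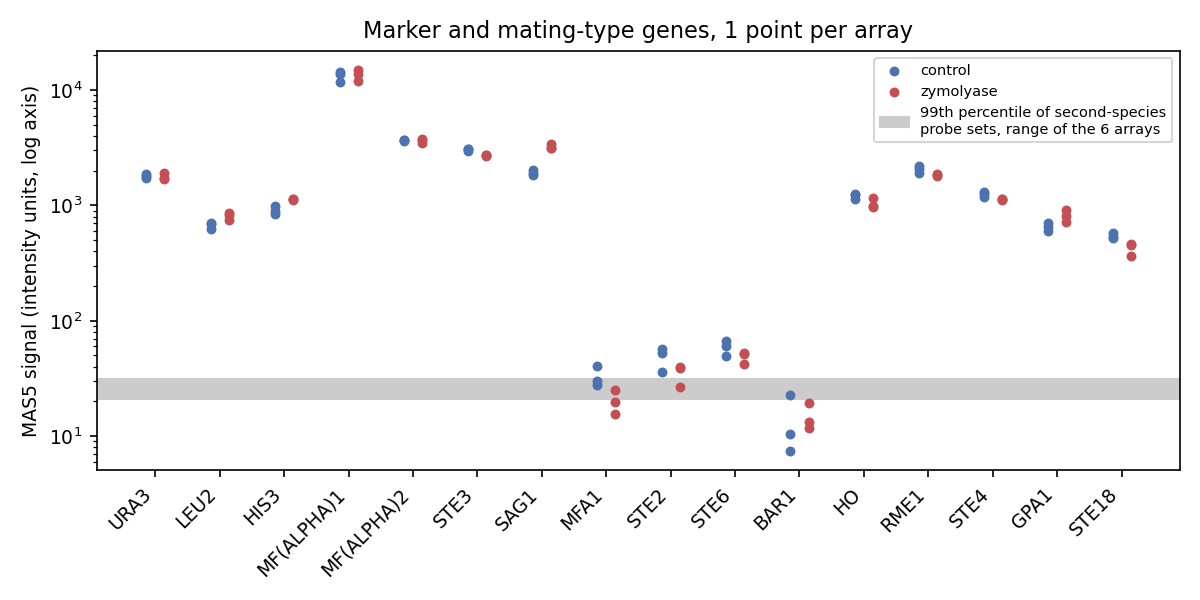
Signal of marker and mating-type genes on each of the 6 arrays (y axis, intensity units, log axis; blue, control; red, zymolyase), with the grey band giving the range over arrays of the second-species 99th percentile, 21.0 to 31.4. URA3, LEU2 and the α-type genes lie far above the band on every array, and the a-type genes MFA1, STE2, STE6 and BAR1 lie near it or below it.

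Zymolyase was followed by a broad shift in transcript signal. Among the 5394 probe sets, 3857 passed the limma test, of which 1759 were higher and 2098 were lower with zymolyase. The median size of a called change was 0.57 on the log2 scale. At least 2-fold changes were found for 554 probe sets, 435 higher and 119 lower, and this count was 321 when 50 was added to every signal before taking logs. In 73.3% of the probe sets the ranges of both groups did not overlap, against 10% by chance for 3 against 3 arrays.

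The named rises were led, among genes bright in both groups, by MPC3, a subunit of the mitochondrial pyruvate carrier, whose signal went from 238 ± 41.4 to 1795 ± 187 (log2 fold change 2.92 ± 0.12 SE, adjusted p = 9.0e-10). The cell wall mannoprotein genes TIR4 and TIR1 rose from 34.7 ± 12.2 to 208 ± 25.7 and from 379 ± 21.5 to 1816 ± 151. PRY3, a wall-associated protein, rose from 333 ± 50.2 to 1742 ± 91.4. RPO21, the largest subunit of RNA polymerase II, rose from 435 ± 63.7 to 1834 ± 125, and RNR3, a subunit of ribonucleotide reductase, from 73.7 ± 5.42 to 320 ± 11.3. Further rises were those of YKR075C (2.29 ± 0.13), ATG41 (2.27 ± 0.10) and PTK1 (2.20 ± 0.13), given as log2 fold change ± SE, where ATG41 acts in autophagy and PTK1 is a protein kinase. Several rises started from control signals not well above background and have only a lower bound. DAN1, another wall mannoprotein, was at least 2.43-fold higher (adjusted p = 0.0013), the protein kinase gene RCK1 at least 4.36-fold (8.4e-06) and CDC13, which binds telomeres, at least 1.99-fold (0.0041). RGI2, YBR221W-A and PTH1 also passed the test (adjusted p = 0.046, 0.023 and 0.024) with too little signal over background for a fold.

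Among genes bright in the control, the falls were led by YBR013C, an open reading frame of unknown function, from 351 ± 18.4 to 33.0 ± 12.9 (log2 fold change -3.48 ± 0.22 SE, adjusted p = 2.6e-08), and by MHF1, a histone-fold protein of the kinetochore and of DNA repair, from 1419 ± 68.2 to 228 ± 29.7 (adjusted p = 3.0e-10). BLI1 fell from 203 ± 12.1 to 37.2 ± 6.96, GLO4, a mitochondrial glyoxalase, from 201 ± 15.7 to 49.3 ± 9.12, and YIL014C-A from 1624 ± 56.5 to 461 ± 12.1. TCA17, HTL1 and YOL097W-A had log2 fold changes of -1.72 ± 0.19, -1.68 ± 0.39 and -1.52 ± 0.20 SE. With 50 added to every signal, which shrinks folds of dim probe sets, the log2 fold changes were -1.07 for TCA17, -0.79 for HTL1, -0.92 for YOL097W-A, -2.28 for YBR013C, -1.54 for BLI1 and -1.34 for GLO4, and 1.61 instead of 2.65 for the rise of TIR4. Below background with zymolyase were SPC24, a kinetochore protein, at least 1.93-fold lower (adjusted p = 0.0021), FIG1, a mating protein, at least 1.54-fold (0.022), MAM1, a meiotic protein, at least 1.31-fold (0.024), and LOH1 at least 1.13-fold (0.015). YFL012W and YJL136W-A passed (0.022 and 0.047) without a fold. SNO1, of vitamin B6 synthesis, was below background on 2 of 3 zymolyase arrays and at least 1.27-fold lower (log2 fold change -1.60 ± 0.66 SE as measured, adjusted p = 0.044). Several of these calls, of dim or variable probe sets, rested on few arrays or on the spread model. With any of 4 arrays left out singly the adjusted p of RGI2 was between 0.056 and 0.12, that of YJL136W-A between 0.062 and 0.11 and that of SNO1 between 0.089 and 0.12. Without control replicate 1 it was 0.061 for LOH1, 0.069 for FIG1 and 0.076 for MAM1. FIG1 also lost its call without control replicate 2 (0.057), and MAM1 without control replicates 2 and 3 (0.052 and 0.052). Without an intensity trend in the spread model the adjusted p was 0.11 for RGI2, 0.082 for FIG1, 0.052 for MAM1 and 0.098 for SNO1, and under quantile normalization it was 0.065 for RGI2. Sizes at background also depended on single arrays: without control replicate 3 the measured log2 fold change of RGI2 was 1.31 instead of 3.21, without zymolyase replicate 2 those of SNO1 and MAM1 were -0.71 and -0.92 instead of -1.60 and -1.70, and without zymolyase replicate 3 those of FIG1 and LOH1 were -1.25 and -1.76 instead of -2.66 and -2.96. With the gene length trend removed, SNO1 (adjusted p = 0.09) and YJL136W-A (0.052) also lost their calls.

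Several groups of cell wall genes were mostly higher. Of 17 measured cell wall integrity targets, genes controlled by the Slt2 kinase pathway, 15 rose, 0 fell and 2 did not pass, with 15 and 0 adjusted over the list alone. SLT2 itself, the kinase, rose from 668 ± 43.4 to 1280 ± 61.1 (log2 fold change 0.94 ± 0.07 SE, adjusted p = 7.2e-08). RLM1, the transcription factor it activates, rose from 216 ± 12.7 to 449 ± 12.6, and CRH1, an enzyme that links chitin to glucan, from 826 ± 30.8 to 1673 ± 78.6. The mannoprotein gene CWP1 rose from 2947 ± 218 to 6841 ± 323, PIR1, another wall protein, from 2105 ± 31.4 to 4567 ± 230, and GSC2, a glucan synthase subunit, from 1075 ± 66.2 to 2075 ± 63.5. GSC2 is a long gene, and its log2 fold change of 0.95 was 0.46 with the gene length trend described further on removed (adjusted p = 1.7e-05). PIR3 had a log2 fold change of 0.52 ± 0.08, and PRM10, below background on 2 of 3 control arrays, was at least 1.82-fold higher (adjusted p = 0.0053). KDX1 and PRM5, targets of the same pathway, did not pass, with log2 fold changes of -0.26 ± 0.16 and -0.13 ± 0.10 (adjusted p = 0.16 and 0.25). The list had a median log2 fold change of 0.93 (camera adjusted p = 1.6e-05, adjusted p = 0.21 with an estimated correlation).

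Structural wall mannoproteins rose further than any other list by median. Of 28, 25 rose, 0 fell and 3 did not pass (25 and 0 adjusted over the list alone; median log2 fold change 0.98, camera adjusted p = 6.4e-08, adjusted p = 0.22 with an estimated correlation). Besides DAN1, TIR4 and TIR1, FIT3, a mannoprotein that binds iron siderophores, rose from 162 ± 13.1 to 535 ± 77.9. Both PAU23 and PAU24 entered this list as the present names of older DAN symbols. Of 12 cell separation genes, some of which act on the septum between mother and daughter cells, 11 rose, 1 fell and 0 did not pass (11 and 1 adjusted over the list alone; median log2 fold change 0.95, camera adjusted p = 0.00015, adjusted p = 0.22 with an estimated correlation). They include PRY3, EGT2 (1.46 ± 0.08), the chitinase gene CTS1, from 2377 ± 78.9 to 5998 ± 137, and ASH1 (1.22 ± 0.06), a repressor specific to daughter cells. The enzymes that make glucan, chitin and mannan went both ways. Of 39, 14 rose, 13 fell and 12 did not pass (14 and 13 adjusted over the list alone; median log2 fold change 0.03, camera adjusted p = 0.39, adjusted p = 0.72 with an estimated correlation). Among them PMT2, a protein mannosyltransferase, rose from 1559 ± 17.7 to 4255 ± 107 and CHS2, a chitin synthase, from 246 ± 23.5 to 488 ± 26.6, next to CRH1, while GAS4, near background, had signals of 25.5 ± 1.99 and 11.4 ± 9.56 and did not pass (adjusted p = 0.072), except without zymolyase replicate 3 (0.018) and with 50 added to every signal (0.044).

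**Figure D2:**
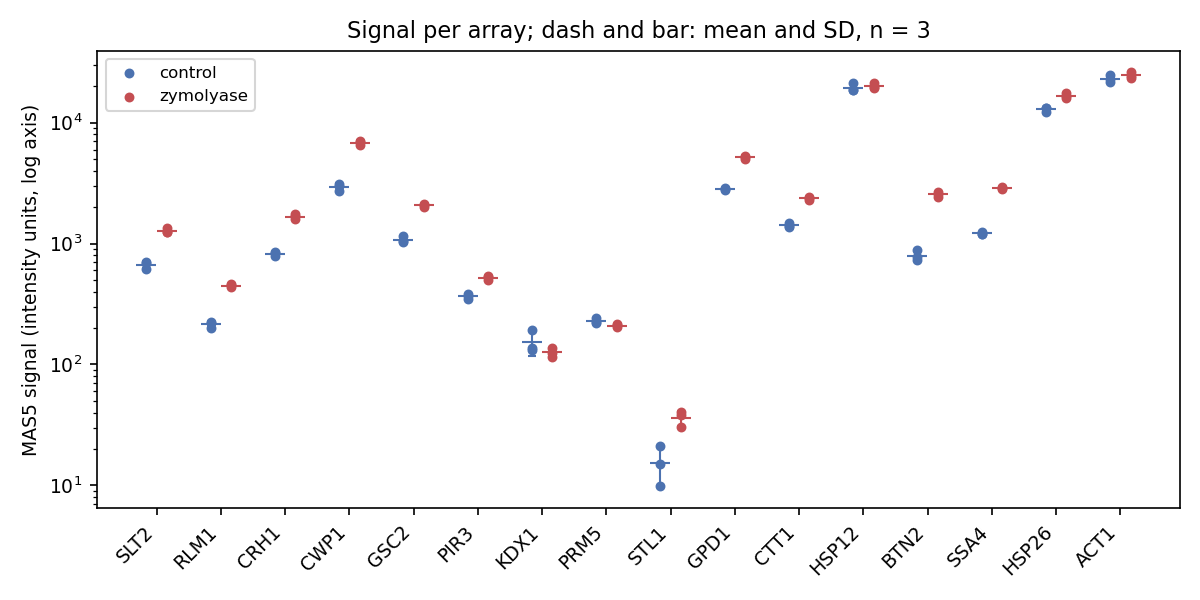
MAS5 signal of named wall, osmotic, stress and heat shock genes (x axis) on each array (y axis, intensity units, log axis; blue, control; red, zymolyase), with dashes and bars for the mean and SD of 3 arrays. SLT2, RLM1, CRH1, CWP1, GSC2, BTN2 and SSA4 are higher on every zymolyase array, while KDX1, HSP12 and ACT1 overlap between groups.

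Most general stress genes and osmotic stress targets were higher as well. The oxidative stress and unfolded protein response lists, given below, did not pass camera with its preset correlation. Of 36 general stress genes, activated through Msn2 and Msn4, 26 rose, 4 fell and 6 did not pass (26 and 4 adjusted over the list alone; median log2 fold change 0.57, camera adjusted p = 1.8e-06, adjusted p = 0.28 with an estimated correlation). XBP1, a transcriptional repressor, rose from 158 ± 16.4 to 592 ± 42.4, and the metabolic enzymes TKL2, ALD3 and GDB1 had log2 fold changes of 1.69 ± 0.15, 1.59 ± 0.08 and 1.59 ± 0.07. CTT1, the cytosolic catalase, rose from 1420 ± 59.3 to 2370 ± 54.2. Of 20 osmotic stress targets of the HOG pathway, 14 rose, 2 fell and 4 did not pass (14 and 2 adjusted over the list alone; median log2 fold change 0.55, camera adjusted p = 0.0026, adjusted p = 0.21 with an estimated correlation). GPD1, which makes glycerol, rose from 2824 ± 42.9 to 5185 ± 173, RTC3 had a log2 fold change of 1.32 ± 0.07, and STL1, a glycerol transporter not well above background in the control, was at least 1.60-fold higher (adjusted p = 0.014, and 0.051 without zymolyase replicate 3). HSP12, a bright gene of both lists and a short one, had signals of 19544 ± 1480 and 20066 ± 1010 (log2 fold change 0.04 ± 0.07 SE, adjusted p = 0.61). With the gene length trend removed, its log2 fold change was 0.35 (adjusted p = 0.00091).

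Of 29 heat shock genes controlled by Hsf1, 22 rose, 6 fell and 1 did not pass (22 and 6 adjusted over the list alone; median log2 fold change 0.44, camera adjusted p = 0.00018, adjusted p = 0.21 with an estimated correlation). BTN2, a factor in the sorting of misfolded proteins, rose from 795 ± 76.6 to 2549 ± 107, and the chaperone genes SSA4, MDJ1 and STI1 had log2 fold changes of 1.24 ± 0.05, 1.12 ± 0.05 and 1.12 ± 0.05. HSP26, a small heat shock protein, rose from 12917 ± 470 to 16783 ± 802 (log2 fold change 0.38, and 0.67 with the gene length trend removed). The median of the cell wall integrity list exceeded that of the heat shock list by 0.49 on the log2 scale (two-sided exact permutation test over 6 arrays, p = 0.1, the smallest this design allows). That comparison cannot reach a p under 0.05, and it cannot separate temperature from enzyme, as a temperature step would reach the wall genes too.

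**Figure D3:**
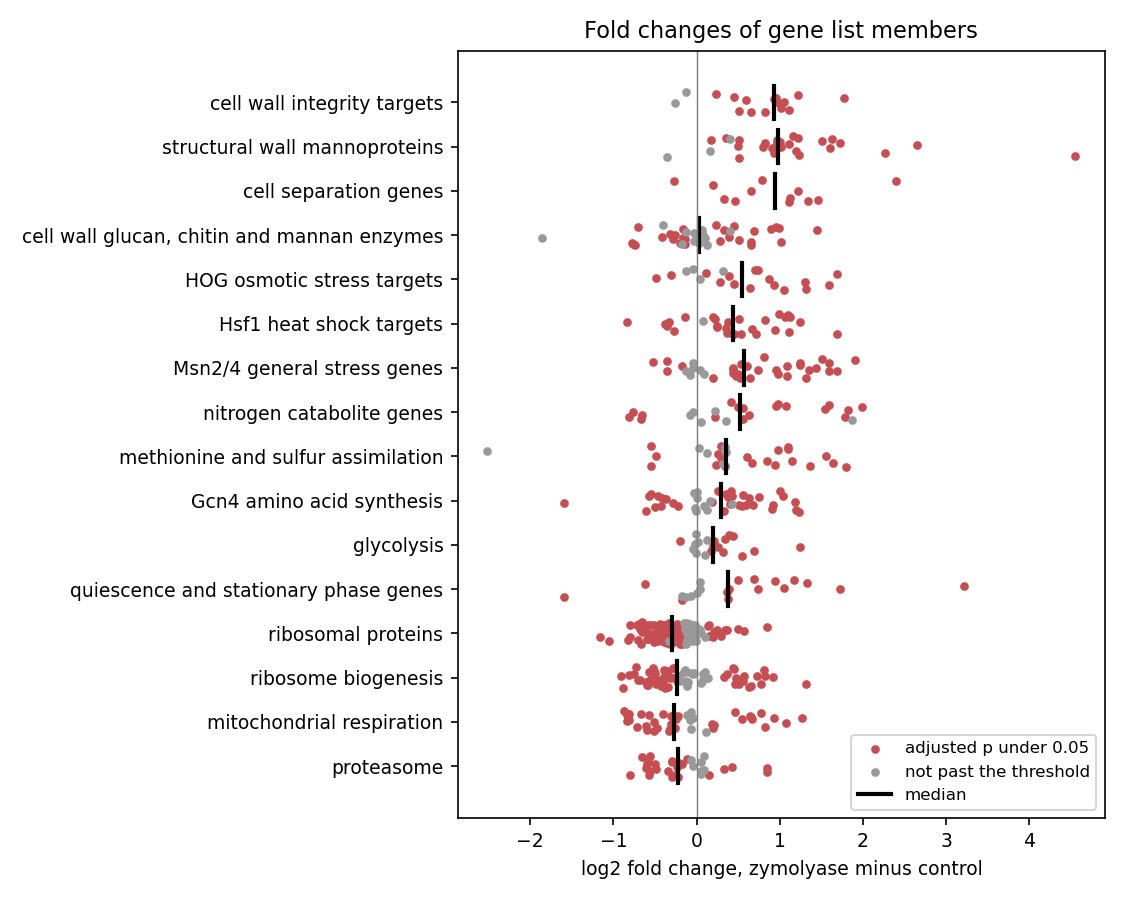
Log2 fold change, zymolyase minus control (x axis), of each measured member of 16 gene lists (y axis). Red points passed the test, grey points did not, and black bars are list medians, which are 0.93 for cell wall integrity targets, 0.98 for structural wall mannoproteins and -0.30 for ribosomal proteins.

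Several metabolic lists also passed upward. Of 24 nitrogen catabolite genes, used with poor nitrogen sources, 14 rose, 4 fell and 6 did not pass (14 and 4 adjusted over the list alone; median log2 fold change 0.53, camera adjusted p = 0.012, adjusted p = 0.28 with an estimated correlation). GAT1, an activator of this group, rose from 164 ± 7.52 to 652 ± 24.1, CAR2 from 272 ± 10.7 to 958 ± 25.4 and the ammonium transporter gene MEP1 from 36.9 ± 3.08 to 127 ± 13.1, while DAL4 was near background (adjusted p = 0.17). Of 26 genes of methionine and sulfur assimilation, 17 rose, 3 fell and 6 did not pass (17 and 3 adjusted over the list alone; median log2 fold change 0.35, camera adjusted p = 0.0036, adjusted p = 0.28 with an estimated correlation). MET2, STR3 and CYS3 had log2 fold changes of 1.79 ± 0.16, 1.65 ± 0.25 and 1.55 ± 0.05. SUL1, at background in both groups, had an adjusted p of 0.087, and of 0.017 without zymolyase replicate 3. Of 42 Gcn4-controlled genes of amino acid synthesis, 22 rose, 11 fell and 9 did not pass (22 and 11 adjusted over the list alone; median log2 fold change 0.30, camera adjusted p = 0.031, adjusted p = 0.28 with an estimated correlation). The largest shifts were the fall of SNO1, given above, and the rises of ARO1 (1.23 ± 0.05), ILV6 (1.20 ± 0.09) and LYS4 (1.19 ± 0.09). The call of this list was lost when the gene length trend was removed (adjusted p = 0.057). Of 19 glycolytic genes, 11 rose, 1 fell and 7 did not pass (11 and 1 adjusted over the list alone; median log2 fold change 0.19, camera adjusted p = 0.032, adjusted p = 0.58 with an estimated correlation), with GLK1 (1.24 ± 0.05), PFK2 (0.68 ± 0.05), PDC5 (0.55 ± 0.10) and HXK1 (0.44 ± 0.05). The glycolysis call was lost with median centring (adjusted p = 0.066), without control replicate 2 (0.062), without zymolyase replicate 2 (0.074) and with the length trend removed (0.052).

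Ribosomal protein genes were mostly lower. Of 128 ribosomal protein genes, 12 rose, 88 fell and 28 did not pass (12 and 90 adjusted over the list alone; median log2 fold change -0.30, camera adjusted p = 1.4e-05, adjusted p = 0.46 with an estimated correlation). The list was drawn by gene name and also holds RPP1, a subunit of RNase P, which is 1 of the rises. RPS17B fell from 16084 ± 1686 to 7186 ± 363, RPS28B had a log2 fold change of -1.05 ± 0.06 and RPL33B of -0.83 ± 0.07, while RPL4B rose (0.84 ± 0.08). These genes are short, with a median length of 771 nt, and with the gene length trend removed the median was -0.09 and the call was lost (adjusted p = 0.7), as 27 members rose and 47 fell. Of 70 ribosome biogenesis genes, 18 rose, 37 fell and 15 did not pass (18 and 37 adjusted over the list alone; median log2 fold change -0.24, camera adjusted p = 0.22, adjusted p = 0.62 with an estimated correlation), with ERB1 (1.32 ± 0.12), NOP2 (0.92 ± 0.07), TIF6 (-0.91 ± 0.06) and EBP2 (-0.88 ± 0.07). With the trend removed this list passed downward (median -0.34, adjusted p = 0.041).

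The other lists are given with their median log2 fold change and the camera adjusted p, first with the preset and then with an estimated correlation, and with members as log2 fold change ± SE. Of 45 genes of mitochondrial respiration, 13 rose, 26 fell and 6 did not pass (14 and 27 adjusted over the list alone; median -0.27, adjusted p = 0.16 and 0.34), with KGD1 (1.27 ± 0.05), SDH1 (1.08 ± 0.06), QCR2 (0.93 ± 0.06) and ATP17 (-0.87 ± 0.09). These genes are short, with a median length of 639 nt. With the length trend removed, 12 of them rose and 19 fell (median -0.01), and 10 of the falls lost their call. Of 32 proteasome genes, 5 rose, 20 fell and 7 did not pass (5 and 20 adjusted over the list alone; median -0.22, adjusted p = 0.079 and 0.28), with RPN10 (0.84 ± 0.06), PUP1 (0.84 ± 0.05), PRE4 (-0.80 ± 0.06) and PUP3 (-0.66 ± 0.05). Of 14 genes of gluconeogenesis and the glyoxylate cycle, 7 rose, 2 fell and 5 did not pass (7 and 2 adjusted over the list alone; median 0.45, adjusted p = 0.22 and 0.38), with ALD4 (1.73 ± 0.05), MLS1 (0.97 ± 0.23) and CAT8 (0.69 ± 0.24). ADH2, below background on 2 of 3 control arrays, was at least 1.65-fold higher (adjusted p = 0.031). The call of ADH2 was lost under quantile normalization (adjusted p = 0.061) and with any of 4 arrays left out singly (between 0.063 and 0.089), and that of CAT8 under quantile normalization (0.051), without control replicate 2 (0.056), without zymolyase replicate 2 (0.07) and with the length trend removed (0.34). Of 17 genes of fatty acid oxidation, 5 rose, 6 fell and 6 did not pass (5 and 6 adjusted over the list alone; median -0.09, adjusted p = 0.94 and 0.96), with TES1 (1.01 ± 0.13), PXA1 (-0.85 ± 0.17), CAT2 (0.63 ± 0.13) and IDP3 (-0.63 ± 0.18). Of 26 genes of ergosterol synthesis, 8 rose, 11 fell and 7 did not pass (8 and 11 adjusted over the list alone; median -0.09, adjusted p = 0.91 and 0.95), with NCP1 (1.32 ± 0.05), ERG12 (0.88 ± 0.08), HMG2 (0.82 ± 0.09) and CYB5 (-0.77 ± 0.07). Of 26 Yap1 oxidative stress targets, 13 rose, 8 fell and 5 did not pass (13 and 8 adjusted over the list alone; median 0.20, adjusted p = 0.14 and 0.28), with ZWF1 (1.71 ± 0.06), OYE2 (1.32 ± 0.05), AAD14 (-0.98 ± 0.22) and CCP1 (0.96 ± 0.06). The Yap1 list passed upward with the length trend removed (adjusted p = 0.035). Of 20 genes of the unfolded protein response, 8 rose, 9 fell and 3 did not pass (8 and 9 adjusted over the list alone; median -0.06, adjusted p = 0.91 and 0.94), with DER1 (-1.34 ± 0.07), SEC61 (1.30 ± 0.06), SCJ1 (1.20 ± 0.07) and HRD3 (1.12 ± 0.09). Of 19 genes of the iron regulon, 11 rose, 3 fell and 5 did not pass (11 and 3 adjusted over the list alone; median 0.48, adjusted p = 0.079 and 0.28), with FIT3 (1.72 ± 0.11), FET3 (1.33 ± 0.08) and FIT1 (1.19 ± 0.20). HMX1, below background on 2 of 3 control arrays, was at least 2.36-fold higher (adjusted p = 0.00082). Of 18 genes reported as targets of the phosphate regulator Pho4, 6 rose, 7 fell and 5 did not pass (6 and 7 adjusted over the list alone; median -0.04, adjusted p = 0.91 and 0.94), with PHM6 (-0.97 ± 0.12) and PHO8 (0.91 ± 0.06). The list also holds CTF19, a kinetochore gene and 1 of its rises, which was below background on 2 of 3 control arrays and at least 2.11-fold higher (adjusted p = 0.0039). PHO89, variable between arrays, had an adjusted p of 0.088, and of 0.026 and 0.036 without control replicates 2 and 3. Of 25 autophagy genes, 7 rose, 11 fell and 7 did not pass (7 and 11 adjusted over the list alone; median -0.12, adjusted p = 0.69 and 0.72), with ATG2 (1.69 ± 0.12), ATG18 (1.22 ± 0.13), PRB1 (1.22 ± 0.05) and ATG12 (-1.19 ± 0.09). 

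Of 29 genes of the G1/S transition and S phase, 13 rose, 12 fell and 4 did not pass (13 and 12 adjusted over the list alone; median 0.09, adjusted p = 0.58 and 0.64), with MCM3 (1.26 ± 0.09), MCM7 (0.90 ± 0.09), CLN2 (0.85 ± 0.09) and RFA3 (-0.81 ± 0.08). Of 19 genes of G2/M, 9 rose, 4 fell and 6 did not pass (9 and 5 adjusted over the list alone; median 0.25, adjusted p = 0.22 and 0.46), with CHS2 (0.99 ± 0.09), HST3 (0.88 ± 0.11), DBF2 (0.77 ± 0.09) and BUD4 (0.75 ± 0.07). With the length trend removed, 5 of the G2/M genes rose and 5 fell (median -0.10). Of 9 histone genes, 1 rose, 6 fell and 2 did not pass (1 and 6 adjusted over the list alone; median -0.30, adjusted p = 0.22 and 0.68), with HHO1 (1.15 ± 0.06), HHT1 (-0.57 ± 0.09), HHF1 (-0.45 ± 0.07) and HTA1 (-0.35 ± 0.05). With the length trend removed, 2 histone genes rose and 1 fell (median 0.01). Of the 6 falls, 5 lost their call, HHF1 and HTA1 among them (adjusted p = 0.063 and 0.54). Of 16 genes of the DNA damage response, 5 rose, 6 fell and 5 did not pass (5 and 6 adjusted over the list alone; median -0.06, adjusted p = 0.69 and 0.72), with RNR3 (2.12 ± 0.12), RAD16 (1.06 ± 0.11), RFX1 (0.99 ± 0.10) and RNR1 (0.79 ± 0.05). Of 9 genes often used as references, 5 rose, 3 fell and 1 did not pass (5 and 3 adjusted over the list alone; median 0.14, adjusted p = 0.52 and 0.72), with RPO21 (2.08 ± 0.09), PDA1 (0.80 ± 0.06), TAF10 (-0.73 ± 0.06) and TFC1 (0.58 ± 0.07). ACT1, the actin gene, had signals of 23072 ± 1546 and 24743 ± 1609 (adjusted p = 0.2). Of 5 auxotrophic marker genes, 4 rose, 0 fell and 1 did not pass (4 and 0 adjusted over the list alone; median 0.29, adjusted p = 0.12 and 0.34), with LYS2 (0.77 ± 0.07), HIS3 (0.32 ± 0.07), MET17 (0.29 ± 0.05) and LEU2 (0.28 ± 0.07). This list passed upward with the length trend removed (adjusted p = 0.043). Lists of other cell states were included because a culture can hold more than dividing cells. Of 21 genes of quiescence and stationary phase, 12 rose, 3 fell and 6 did not pass (12 and 3 adjusted over the list alone; median 0.38, adjusted p = 0.044 and 0.28), with ALD4 (1.73 ± 0.05) and SPG4 (1.33 ± 0.24). RGI2 and SNO1, given above, are also among its largest shifts. The call was lost without control replicate 2 (adjusted p = 0.062), without zymolyase replicate 2 (0.056), without zymolyase replicate 3 (0.051) and with the stricter background filter (0.053). It was also lost with the replicate number as a block. Of 28 genes of mating and of haploid cells, 5 rose, 8 fell and 15 did not pass (5 and 7 adjusted over the list alone; median -0.11, adjusted p = 0.94 and 0.95), with KAR4 (-1.27 ± 0.09) and FIG2 (0.90 ± 0.14). PRM2, below background with zymolyase, had an adjusted p of 0.087, and of 0.041 without zymolyase replicate 1. Of 30 meiosis and sporulation genes, 1 rose, 6 fell and 23 did not pass (1 and 4 adjusted over the list alone; median -0.42, adjusted p = 0.38 and 0.46). With the length trend removed, 1 of them rose and 12 fell (median -0.49). REC104, below background with zymolyase, was at least 2.27-fold lower (adjusted p = 0.00035). DIT2, REC102 and GAS4 were near background (adjusted p = 0.059, 0.062 and 0.072). DIT2 passed without control replicate 3 (0.012) and without a background filter (0.041), and REC102 without zymolyase replicate 1 (0.013) and with 50 added to every signal (0.042). No mitochondrially encoded gene was measured. With 50 added to every signal, the log2 fold changes of dim list members given above were 0.51 for MLS1, 0.33 for CAT8, -0.39 for IDP3, -0.63 for AAD14, 1.18 for MET2, 0.85 for STR3, 0.67 for FIT1, 1.03 for MEP1 and 0.76 for SPG4. In all, 12 of 32 lists passed camera with its preset correlation, 11 upward and 1 downward. The passing lists are not independent of each other, since several share members. The wall integrity and mannoprotein lists share CWP1, PIR1, PIR3, CIS3, HSP150 and SED1. Among those shared by the Msn2/4 and HOG lists are CTT1, HSP12 and ALD3. With an estimated correlation camera passed 0 of 32, 5 having an unadjusted p under 0.05, and fry passed 28. In the other 9 splits of the 6 arrays into 3 and 3, camera with its preset passed 5 to 10 lists. Those splits keep part of the real contrast, so this is not a rate of false calls.

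Measures of RNA quality also moved with the groups. The ACT1 ratio of 3' to 5' control probe sets was 2.04 ± 0.162 in the control and 2.44 ± 0.106 with zymolyase, 1.20 times higher (two-sided exact permutation test, p = 0.1, the smallest possible). Of 8 genes with such probe sets, 6 had a higher ratio on every zymolyase array than on any control array, the smallest difference being 1.07 times for TDH1. The SRB4 ratios were 12.2, 30.5 and 11.2 on the zymolyase arrays against 6.51 ± 0.323 in the control, so their size rests much on a single array. WBP1 and EAF5 had ratios 1.18 and 1.28 times higher with overlapping arrays (exact permutation p = 0.3 and 0.8). Of 17 control probe sets for ribosomal RNA, 13 were lower on every zymolyase array than on any control array and 2 were higher. All 8 probe sets for 18S ribosomal RNA were among the lower ones, with a median log2 difference of -1.44. In the 3', middle and 5' series of 25S ribosomal RNA the log2 differences were 0.04, -1.42 and -1.55, and the 3' probe set overlapped between groups. The same series of 18S ribosomal RNA gave -1.51, -0.93 and -1.44, without such a step toward the 5' end.

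The fold change also tended to increase with gene length. Across the 5394 probe sets, Spearman's rho between log2 fold change and coding length was 0.41, where genes are not independent replicates. The median log2 fold change was -0.36 for 1428 genes of 500 to 1000 nt and 0.45 for 188 genes over 4000 nt. Higher genes had a median length of 1659 nt and lower genes of 885 nt. Beside this, the median length was 1302 nt for cell wall integrity targets, 788 nt for structural mannoproteins, 1233 nt for Hsf1 targets, 1182 nt for Msn2/4 genes and 1706 nt for cell separation genes. With the length trend removed on each array, a step chosen after the data were seen, the medians of these lists were 0.80, 1.03, 0.42, 0.53 and 0.75, each still past the threshold of camera with its preset correlation. Of their members 13 rose and 0 fell, 26 rose and 0 fell, 20 rose and 2 fell, 30 rose and 2 fell and 9 rose and 1 fell after this step, in the same order. The same step left 3716 probe sets past the test, 3091 of which also passed without it. It moved the log2 fold change of 24 of 141 called named genes by over 1.5 times. Besides GSC2 and HSP26, these were CHS2 (0.99 and then 0.66), PFK2 (0.68 and then 0.35), PDC5 (0.55 and then 0.35), CAT8 (0.69 and then 0.26), ATP17 (-0.87 and then -0.55), CAT2 (0.63 and then 0.37), PUP3 (-0.66 and then -0.36), HMG2 (0.82 and then 0.47), CYB5 (-0.77 and then -0.45), ARO1 (1.23 and then 0.78), MCM7 (0.90 and then 0.59), RFA3 (-0.81 and then -0.50), HHT1 (-0.57 and then -0.25), HHF1 (-0.45 and then -0.13), HTA1 (-0.35 and then -0.04), BUD4 (0.75 and then 0.32), RNR1 (0.79 and then 0.47), FIG2 (0.90 and then 0.45), TAF10 (-0.73 and then -0.43), TFC1 (0.58 and then 0.33), LYS2 (0.77 and then 0.35) and HIS3 (0.32 and then 0.60).

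**Figure D4:**
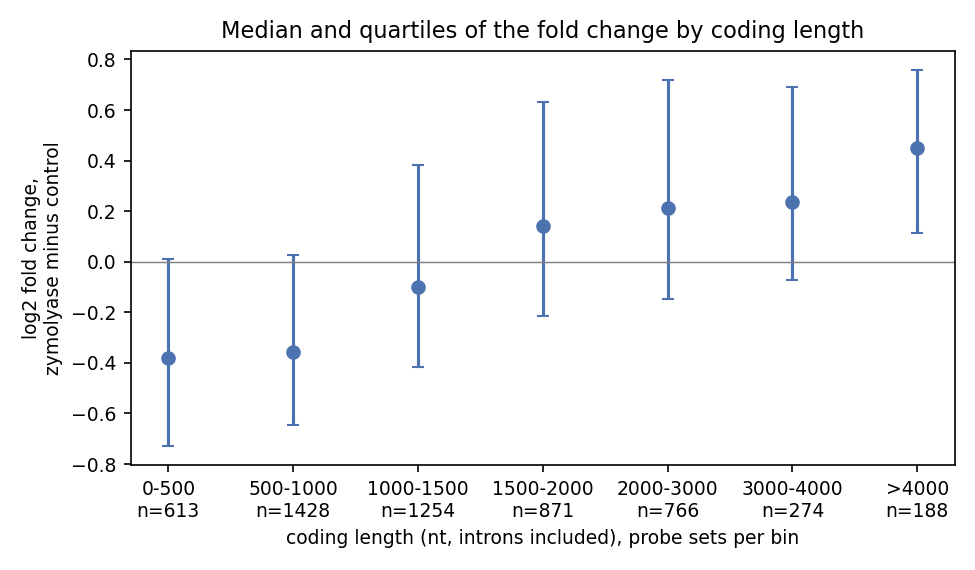
Median log2 fold change, zymolyase minus control (y axis), of tested probe sets in bins of coding length in nt (x axis), with bars from the lower to the upper quartile over genes. Medians run from -0.38 in the shortest bin to 0.45 above 4000 nt.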

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

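The test of unnamed probe sets was chosen after the data were seen. Probe sets that the annotation used here does not list enter no comparison above. Of 3517, 568 exceeded the background signal, and limma called 57 of them higher and 86 lower with zymolyase at an adjusted p of 0.05. Of the named probe sets tested, 71.5% were called. The 57 higher ones are signals above the control level outside the named genes. The largest called fall went from signals between 178 and 201 in the control to between 19.8 and 36.8 with zymolyase. The largest called rise went from between 37.1 and 52.8 to between 191 and 203. The 568 include array control probe sets with other name prefixes. Which transcripts the others are was not analysed here.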

How the results depend on the processing

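The length, probe-set and RNA integrity array alternatives were chosen after the data were seen. The counts of changed, higher and lower genes stayed within 1.5 times of their values in each alternative: from 3625 to 3933 changed, including 3625 to 3758 without any single array, with no called gene of both fits opposite in sign except 24 with the gene length trend removed and 31 when the block was added to that. The count of at least 2-fold changes was 321 with an offset of 50, which by construction shrinks folds of dim probe sets, and 409 to 589 otherwise. The number of lists past the threshold was 0 with an estimated correlation, 28 by fry, which asks another question, and 10 to 13 otherwise. Wall minus heat shock list medians ranged from 0.38 to 0.52 and the ACT1 ratio stayed above 1. Among named genes that passed, an offset of 50 moved 35 of 141 log2 fold changes by over 1.5 times and length removal 24. None reversed direction with a call in either fit. Leaving out probe sets that can match several transcripts gave 3795 changed genes and 12 lists. Same-numbered arrays did not deviate together: correlations of deviations were 0.05, 0.07 and 0.02, so the numbers were not read as pairs, although 2 of 3 zymolyase arrays correlated best with their own number. With the replicate block, 3933 genes were changed, and 11 lists passed. With it the quiescence list and YJL136W-A lost their calls and PHO89 gained its call. Signal over background limits genes near a signal of 10 to 30, where single arrays decide calls.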

Other observations

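The lists of anaerobic, actin patch, kinetochore and mating-type genes, all tests of the strain markers, the heat shock comparison as a test of temperature, and the signal-level and 3' to 5' tests of the length trend were chosen after the data were seen. The length trend itself was noticed in the data, and the ribosome biogenesis test of it and the other-split test were written before their results were seen. Genes of the cortical actin patch and endocytosis, a list not independent of the values that prompted it, were mostly higher with zymolyase. Of 41, 29 rose, 8 fell and 4 did not pass (median log2 fold change 0.49, and 0.47 with the gene length trend removed). PAN1, a scaffold of endocytic sites, rose from 510 ± 44.0 to 1938 ± 8.43, the actin-binding ABP1 from 808 ± 5.60 to 2793 ± 116, the myosin MYO5 from 375 ± 28.5 to 1218 ± 25.9 and LAS17, an activator of actin branching, from 93.4 ± 7.61 to 277 ± 18.6. Subunits of the Arp2/3 complex went both ways: ARP3 and ARC40 rose (1.04 ± 0.05 and 0.24 ± 0.09 log2, SE), ARC35, ARC19, ARC15 and ARC18 fell (-0.50 ± 0.11, -0.63 ± 0.06, -0.48 ± 0.06 and -0.36 ± 0.05) and ARP2 did not pass (-0.03 ± 0.07). With the length trend removed, 6 of the 29 rises and 2 of the 8 falls of the list lost their call, ARC18 among them, and 23 rose and 7 fell.

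The kinetochore and anaerobic lists also hold genes that prompted them, so no test of these whole lists is given. Of 40 kinetochore genes, 6 rose, 29 fell and 5 did not pass (median log2 fold change -0.58). With the length trend removed 5 rose and 26 fell (median -0.56). Besides MHF1 and SPC24, which are among the largest falls, MCM22 fell from 204 ± 13.8 to 83.5 ± 5.99, IML3 from 377 ± 30.0 to 157 ± 12.7 and DAD1 from 1360 ± 56.8 to 719 ± 28.1. Of the 24 genes listed as anaerobic or as linked to the regulators Rox1 and Upc2, 9 are DAN, TIR and PAU wall proteins. These include DAN1, TIR4 and TIR1. Of the other 15, 9 rose, 2 fell and 4 did not pass (median log2 fold change 0.35). Their camera adjusted p, over 5 lists added after the data were seen, was 0.038 (unadjusted p = 0.030), and the call was lost with the length trend removed (0.079) and with an estimated correlation (0.12). The lists prompted by the values are among those 5, and their small p-values make this adjustment lenient, so the call carries little weight. The 15 genes still hold ROX1, the gene of the repressor Rox1 itself and not a gene listed as anaerobic. It also prompted the list, rose from 113 ± 27.4 to 361 ± 11.1 and is counted among the 9 rises. The heme synthesis gene HEM13 rose from 1264 ± 78.5 to 2152 ± 64.7. The short genes COX5B and CYC7 fell (-0.72 ± 0.05 and -0.36 ± 0.07 log2, SE). With the length trend removed, 8 of the 15 rose and 3 fell: CYC7 and the long rises PDR11 and MGA2 lost their calls (adjusted p = 0.58, 0.071 and 0.87), COX5B was at -0.41, and AUS1 and OLE1 passed as falls (-0.61 and -0.21).

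Longer genes tended to be higher and shorter genes lower, with a Spearman rho of 0.41 over all probe sets. Signal differences between 3 equal classes of probe sets by signal do not account for all of this. Spearman's rho was 0.22 in the class of lowest signal, 0.46 in the middle class and 0.57 in the class of highest signal. The trend was thus stronger at higher signal, and signal still varies within each class. Functional classes of different length do not account for all of the length trend either. Within the ribosome biogenesis list rho was 0.42 (permutation test over 70 genes, p = 0.00035, genes taken as independent). Shortened RNA or lower 5' coverage in the treated arrays is left open: the 3' to 5' ratio was higher on every zymolyase array for 6 of 8 control genes, but a loss of signal far from the 3' end gives no reason for long genes to rise, and the positions of the probes were not analysed here. A response of the cells to zymolyase that depends on transcript length also stays open and was not tested.

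The strain labelled BY4743 gave URA3 and LEU2 signals on every array. Cross-hybridisation or background is argued against by the lowest of 4 URA3 probe sets, still 29.3 times the second-species 99th percentile of its array, and a single mixed or swapped array by a highest-to-lowest ratio of at most 1.38 over both genes. Cells of another genotype and mating type than labelled are a candidate explanation. The 4 α-specific genes had a median of 136 times the background percentile, the 8 haploid-specific genes 25.7 times, and the 6 a-specific genes 0.80 times, which is consistent with haploid or homozygous α cells rather than a/α cells. A plasmid carrying the markers was not tested and would not by itself give the mating-type signals.

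Most Hsf1 heat shock targets rose, 22 of 29 with 6 falls, and the list did not pass camera with an estimated correlation (adjusted p = 0.21). That correlation was -0.011, below the preset of 0.01, so a higher correlation between members is not what ended the call. The HOG list, with an estimated correlation of -0.034, lost its call in the same way. With an estimated correlation camera also takes its degrees of freedom from the few arrays, which by itself raises the p. The step to the treatment temperature cannot be told apart from the enzyme for this or any other list, because the labels do not give the temperature of the control cells. The wall integrity list rose by 0.49 more than the heat shock list. A temperature step would reach the wall genes too, so this difference cannot decide, and such a step stays possible for both lists.

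The 6 arrays make only 10 splits into 3 and 3, so no share under 0.05 can be had. In 1 of 10 splits, the real one, 3857 genes were changed, 1759 higher, 2098 lower and 554 at least 2-fold, and the highest of the other splits was 0 by limma for each, with at most 33 genes at an unadjusted p under 0.05. For the lists the real split gave 12 past the threshold and the highest of the others 10. The other splits keep part of the real contrast, since each leaves 2 arrays of a group on a side. The rest of the contrast lies within their sides, which by itself lowers the limma counts. None of these counts is therefore a rate of false calls.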
